A study of Mus musculus with 15 samples.

How the data were processed

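Poly(A)+ RNA was selected from total RNA of mouse eyes with their eyelids and sequenced on the Illumina HiSeq 2000 after 18 cycles of PCR. The labels describe fixation of eyes in glutaraldehyde and formalin in one place and storage in RNAlater in another, and whether any sequenced eye had been fixed is not clear from them. The mice were BALB/c. An Egr1-/- line on C57BL/6 had been backcrossed to BALB/c for 5 generations in a first series and 4 in a second. Adaptors were ligated to double-stranded cDNA, a method that does not keep the strand of the RNA. Per the labels, the authors' processing named CASAVA 1.8, Bowtie 0.12.9, TopHat2 2.0.11, SAMtools and the mouse build mm8. The labels do not say which annotation release or counting tool was used.

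The deposited table of each library held 24373 RefSeq transcripts with 20418 gene symbols. It gave the authors' raw read counts per transcript and their RPKM values (reads scaled to exon length and library size), which rested on a library total chosen by the authors. These totals were recovered from the count, exon length and RPKM of each transcript. The deposited tables named no sequencing batch. Several transcripts shared a symbol for 2673 genes. The transcript with the highest mean count was taken for each symbol, a choice made after the tables had been seen. Reads of near-identical paralogs (Sprr2, Serpinb3, Stfa, Cryg, Lce, Krt6a and Krt6b) may have been shared, so that values of single members of these families are uncertain. The strain of the mice also differs from that of the reference genome. A reference annotation of a later build served only to find which genes lie near Egr1, and no coordinates were taken from it.

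Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood test), at a Benjamini-Hochberg adjusted p threshold of 0.05. Values per library are reads scaled to the TMM-adjusted library total (CPM). The SE of a log2 fold change was its size divided by the square root of the F statistic. The 4 newborn and 3 adult libraries shared 1 fit with a mean per group, which gave the newborn, adult and age contrasts and the difference of the genotype effect between ages. A second fit of these 7 libraries held age as a term and 1 genotype effect. The lone adult wild-type library was assumed to vary like the other groups. At day 3, the 8 eyes were fitted with the mouse as a block. For labelled-knockout against heterozygous mice, the reads of the 2 eyes of each mouse were summed, and the lone heterozygous mouse was assumed to vary like the others. The adult and newborn labels name no animals, so that p-values there measure the spread between libraries. Replicate numbers were not used as pairs: across genes, the difference between newborn wild-type replicates 1 and 2 had a correlation of 0.0800 with that between the labelled-knockout replicates.

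A total of 30 gene lists was fixed before the data were examined, together with the comparisons, tests, alternatives and the rule for naming genes. The lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry. The p-values were adjusted over the lists of a comparison. A list adjusted p printed without mention of an estimated correlation is that at the preset correlation. It cannot be set against an adjusted p with an estimated correlation, which is printed for most lists that passed at the preset one. Genes of a list are counted as passing among all genes tested and, separately, when adjusted over the list alone. Named in each comparison were Egr1, then up to 10 genes with the largest rise and 10 with the largest fall. These had to pass the test, to reach a mean of 1 RPKM in the higher group and to have every library of one group above every library of the other. For open against closed eyelids, the same direction in both mice with 1 open and 1 closed eye was asked instead. Left out were predicted genes known only by an ID, Y-linked genes and Xist. Up to 4 members of a described list with the smallest p were named besides. Where fewer than 5 genes passed, the 5 smallest p-values in each direction were named as values that did not pass. Some genes that met the rule are not reported here. Genes named outside this rule, which were chosen after their values were seen, are Cryaa, Krt10, Lor, Xist, Ddx3y, Gapdh, Rpl24, Rps6 and those with a sharp step between eyelid states.

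Alternatives were size factors in place of TMM, no filter or a mean of at least 5 RPKM, the Wald test of DESeq2 1.42.0, each library or mouse left out in turn, a replicate block, other models for the mouse and subsets of samples. Alternatives with another pseudocount were planned for RPKM only and did not apply to counts. Added after seeing the data were all transcripts in place of 1 per gene, the authors' library totals, and libraries without lens genes. The list tests were also repeated without single libraries or mice, for the adult lists and the wound and stress list, after seeing the data. The tests were checked on simulated counts with the design of each comparison. Of 100 genes changed 4-fold, 71 were recovered in the newborn design, 50 in the adult and 70 in the fit over both ages. For the difference between ages 16 were recovered, 66 for age, 61 for the eyelid and 0 for the heterozygous mouse. Unchanged genes called in these runs numbered 15 (newborn), 9 (adult) and 15 (both ages). They numbered 7 each for the difference between ages, age and the eyelid, and 0 for the heterozygous mouse. Except for the heterozygous mouse, these were a larger share of all calls than the adjusted p threshold aims for. The counts of called genes may therefore hold more false calls than that threshold implies. For a gene whose libraries were all at 0 reads in a group, the fold was given as a bound against 3 reads over the group. Ratios of genes with 1 to 3 reads in a group carry exact (Clopper-Pearson) 95% intervals, and for the eyelid they were taken over E24 and E29 only. Bounds and intervals cover counting error only, since reads after PCR without molecular identifiers are not independent molecules.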

Results

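RNA of whole eyes, eyelids included, was sequenced to examine the role of Egr1, an immediate-early zinc finger transcription factor, in eyelid development of BALB/c mice. Eyelids of mice normally fuse before birth and reopen later, and some Egr1-/- mice of the series had open eyelids 3 days after birth. The 15 libraries were 1 adult wild type, 2 adult Egr1-/-, 2 newborn wild type, 2 newborn Egr1-/- and 8 single eyes of 4 mice at day 3. Mice E24 and E29 (Egr1-/-) each had 1 open and 1 closed eye, both eyes of E32 (Egr1-/-) were open, and both eyes of E28 (Egr1+/-) were closed. Reads in transcripts came to 24429707 in the adult wild type and to 23667059 and 24061422 in the adult knockouts. Newborn wild types had 20334849 and 25827610, and newborn knockouts 32186113 and 30154706. Open eyes had 36654005 (E24), 39208618 (E29), 39506180 (E32 right) and 33521183 (E32 left). Closed eyes had 34702734 (E24), 33682912 (E29), 43907093 (E28 right) and 31981438 (E28 left).

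The level of Egr1 (chromosome 18) went against the genotype labels. It was 33.0 CPM (reads scaled to library size) in the adult wild type and 46.1 and 60.7 CPM in the newborn wild types. In libraries labelled knockout it was 256 and 184 CPM in adults and 215 and 274 CPM in newborns. Open eyes had 161 (E24), 297 (E29), 341 and 367 CPM (E32), and closed eyes of labelled knockouts 157 (E24) and 221 CPM (E29). The eyes of the heterozygous mouse had 99.3 and 110.3 CPM. In newborn eyes Egr1 rose by 2.18 ± 0.27 (log2 fold change ± SE, n = 2 against 2, adjusted p = 0.00341), and by 2.02 without newborn wild-type replicate 1, where it did not pass (adjusted p = 0.0528). The adult value was 2.76 ± 0.36 (n = 2 against 1, adjusted p = 0.131). Over both ages it was 2.41 ± 0.24 (n = 4 against 3, adjusted p = 0.1), and it passed without adult labelled-knockout replicate 2 (2.46, adjusted p = 0.038) and without the adult wild type (2.15, adjusted p = 0.00441). Without the adult wild type only the newborn libraries inform this contrast, so that it repeats the newborn result. Counts cover the whole transcript, so they do not show whether the allele was disrupted. Groups are named by their labels, as labelled knockout, and every direction is drawn from those labels.

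**Figure D1:**
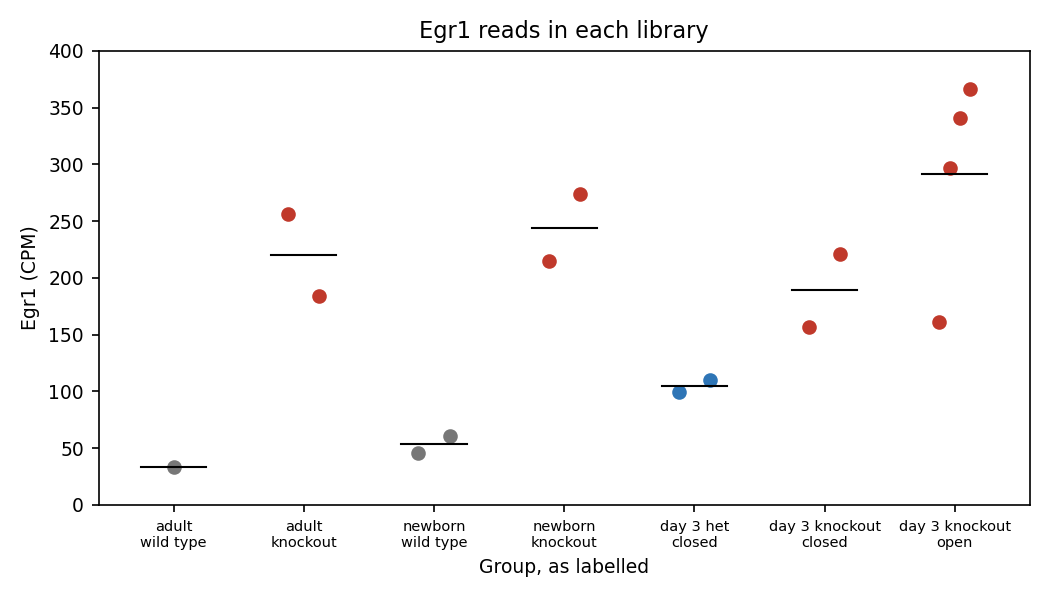
Egr1 level (CPM, y axis) in each of the 15 libraries (points), by group as labelled (x axis), with group means (lines). The 10 labelled-knockout libraries lie between 157 and 367 CPM, above the wild types (at most 60.7 CPM) and the heterozygous eyes (mean 105 CPM).

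The newborn comparison asked which genes differed between labelled-knockout and wild-type eyes at birth (n = 2 each). Genes of stressed and basal epidermis stood out. Sprr1b, a precursor of the cornified envelope, rose by 7.33 ± 0.61 (log2 fold change ± SE), from 0.0903 ± 0.00677 to 15.4 ± 7.58 CPM (mean ± SD). Lamb3 and Lama3, which anchor basal keratinocytes, rose by 3.81 ± 0.27 and 3.60 ± 0.28. Of chemokines that attract neutrophils, Ppbp rose by 6.43 ± 0.99 and Cxcl5 by 6.12 ± 0.73, while Cxcl2, at 0 reads in both wild types, was at least 108-fold higher. The cytokines Il1b and Il24 rose by 6.01 ± 0.87 and 5.92 ± 0.68. Psca (7.76 ± 1.15), Clca4 (7.26 ± 0.57) and Sprr3 (5.82 ± 0.90) rose too, and Sprr2f, with 1 read in the wild types, was higher 62.6-fold (95% interval 10.9 to 2505). Genes of photoreceptors fell, among them recoverin (Rcvrn, -3.00 ± 0.43), Pde6g (-3.19 ± 0.59), Gngt1 (-2.87 ± 0.62), Rdh8 (-3.07 ± 0.39) and Rd3 (-2.90 ± 0.45). The other large falls were Optc (-3.92 ± 0.60), Crhbp (-3.24 ± 0.76), the hair keratin Krt35 (-2.88 ± 0.75) and Gsbs (-2.85 ± 0.46).

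In all, 2576 genes rose and 1650 fell of 17592 tested in newborn eyes (edgeR, 6496 at an unadjusted p under 0.05, DESeq2 5270). The count rested on few libraries. Without newborn wild-type replicate 1 it was 0 by edgeR (smallest adjusted p 0.0517, 4735 genes at an unadjusted p under 0.05), without wild-type replicate 2 it was 728, and without labelled-knockout replicate 1 it was 2089. With the authors' library totals, the median over all genes moved from -0.07 to 0.08 and the calls became 2751 up and 1084 down. The directions of the lists described kept their sign under each scaling. At the preset correlation 17 of the 30 lists passed upward and 6 downward in newborn eyes (camera). With an estimated correlation 0 passed.

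By list, 26 of 27 basal epidermis genes rose in newborn labelled-knockout eyes (median 2.64; 27 adjusted over the list alone; adjusted p = 0.382 with an estimated correlation), with the desmoglein Dsg3 at 3.82 ± 0.32. Of 28 conjunctival and mucosal genes, 23 rose (median 2.99; 24 adjusted over the list alone; adjusted p = 0.382 with an estimated correlation), among them Spink5 (4.49 ± 0.32), Ltf (4.80 ± 0.36) and Krt8 (2.33 ± 0.19). Of 47 keratinocyte wound and stress genes, 28 rose (median 3.02; 35 adjusted over the list alone; adjusted p = 0.0737 with an estimated correlation), with S100a9 at 4.64 ± 0.37, Krt6b at 4.62 ± 0.39 and the urokinase receptor Plaur at 3.10 ± 0.28. Calls over all genes were lost without newborn wild-type replicate 1, as given above (edgeR). The medians of these lists were then 2.26, 2.815 and 3.75. Without wild-type replicate 2 they were 2.96, 3.105 and 3.17, with fewer calls.

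Of 55 cornified epidermis genes, 10 rose, among them Tgm1 (2.42 ± 0.20), Krtdap (2.78 ± 0.42) and Cnfn (3.11 ± 0.50), and Elovl4 fell by 1.65 ± 0.21. The median was 1.81 (9 up and 1 down adjusted over the list alone; adjusted p = 0.704 with an estimated correlation). It was -0.81 without labelled-knockout replicate 1, whose loricrin level (Lor) was 381 CPM against 3.46 CPM in replicate 2. Calls over all genes were lost without wild-type replicate 1 (edgeR), where the median was 1.58. The median was 2.165 without wild-type replicate 2 and 2.47 without labelled-knockout replicate 2. Calls up were fewer without wild-type replicate 2 or labelled-knockout replicate 1, and more without labelled-knockout replicate 2. Of 41 hair follicle genes, 4 fell, among them Krt73 (-1.95 ± 0.44) and Krt26 (-2.49 ± 0.61), and Padi1 rose by 1.58 ± 0.44 (median -1.87; 0 adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). That median was -0.64 without wild-type replicate 2, with 0 genes passing.

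Inflammatory and stromal lists rose in newborn labelled-knockout eyes as well. Of 41 neutrophil and acute inflammation genes, 23 rose (median 3.15; 30 adjusted over the list alone; adjusted p = 0.382 with an estimated correlation), with the interleukin 1 antagonist Il1rn at 3.46 ± 0.25 and Csf3r at 2.85 ± 0.33. Of 33 macrophage genes, 8 rose, led by Cd14 (4.31 ± 0.40) and Itgam (2.93 ± 0.42), and 15 did so adjusted over the list alone (median 1.53; adjusted p = 0.621 with an estimated correlation). Of 29 interferon response genes, 17 rose (median 1.67; 21 adjusted over the list alone; adjusted p = 0.382 with an estimated correlation), with Ifit1 at 2.77 ± 0.31 and Irf7 at 2.98 ± 0.36. Of 45 collagen and matrix genes, 34 rose (median 1.58; 39 up and 2 down adjusted over the list alone; adjusted p = 0.439 with an estimated correlation), with the growth factor receptors Pdgfrb at 1.74 ± 0.21 and Pdgfra at 1.55 ± 0.23. Of 53 skeletal muscle genes, 16 rose (median 1.23; 21 adjusted over the list alone; adjusted p = 0.621 with an estimated correlation), with Myog at 1.59 ± 0.26 and the embryonic myosin Myh3 at 2.22 ± 0.56. Calls over all genes were again lost without wild-type replicate 1 (edgeR). The medians of these lists, in the same order, were then 3.63, 1.74, 1.97, 1.43 and 1.13. Without wild-type replicate 2 they were 2.965, 1.51, 1.42, 1.88 and 1.30, with fewer calls. Muscle genes also lost most of their calls over all genes without either labelled-knockout replicate.

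Of 30 Egr family and other immediate-early genes (Egr1 itself left out), 19 rose and 1 fell (median 0.98; 21 up and 1 down adjusted over the list alone; adjusted p = 0.382 with an estimated correlation), with Fosb at 2.52 ± 0.25, Junb at 2.44 ± 0.23 and Ier3 at 1.91 ± 0.17. Of 42 genes known for a role in eyelid closure of mice, 20 rose and 2 fell (median 0.61; 21 up and 3 down adjusted over the list alone; adjusted p = 0.612 with an estimated correlation). Among them were the activin subunit Inhba (3.15 ± 0.27), Osr2 (2.80 ± 0.28), Foxc1 (2.49 ± 0.29) and the receptor Egfr (2.06 ± 0.24). Calls over all genes in these lists were lost without wild-type replicate 1 (edgeR), where the medians were 0.92 and 0.58. The medians were 1.19 and 0.72 without wild-type replicate 2, with fewer calls.

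Retinal lists fell in newborn labelled-knockout eyes. Of 37 rod genes, 27 fell (median -2.23; 30 adjusted over the list alone; adjusted p = 0.439 with an estimated correlation), with Samd7 at -2.57 ± 0.28. Of 22 cone genes, 12 fell (median -1.50; 16 adjusted over the list alone; adjusted p = 0.382 with an estimated correlation), with Gngt2 at -2.42 ± 0.35. Of 37 inner retina genes, 25 fell, among them Calb2 (-2.44 ± 0.25) and Sncg (-2.03 ± 0.19) (median -1.83; 30 down and 1 up adjusted over the list alone; adjusted p = 0.382 with an estimated correlation). Of 40 progenitor and cell cycle genes, 7 fell (median -0.29; 6 adjusted over the list alone; adjusted p = 0.664 with an estimated correlation), among them the neurogenic factors Neurog2 (-2.49 ± 0.17) and Hes6 (-2.10 ± 0.25) and the growth factor Fgf15 (-2.28 ± 0.22). Without labelled-knockout replicate 1 the rod median was -1.72 and the progenitor median -0.10, and without replicate 2 the rod median was -3.03. Calls over all genes were lost without wild-type replicate 1 (edgeR). The rod, cone, inner retina and progenitor medians were then -2.32, -1.35, -1.78 and -0.32. Without wild-type replicate 2 they were -2.05, -1.91, -1.75 and -0.22, with fewer calls. None of 36 lens genes passed the edgeR test (median -1.18), and 25 fell without labelled-knockout replicate 2. The lens crystallin Cryaa stood at 250.3 CPM in labelled-knockout replicate 1 and between 36240 and 40070 CPM in the other 3 newborn libraries.

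**Figure D2:**
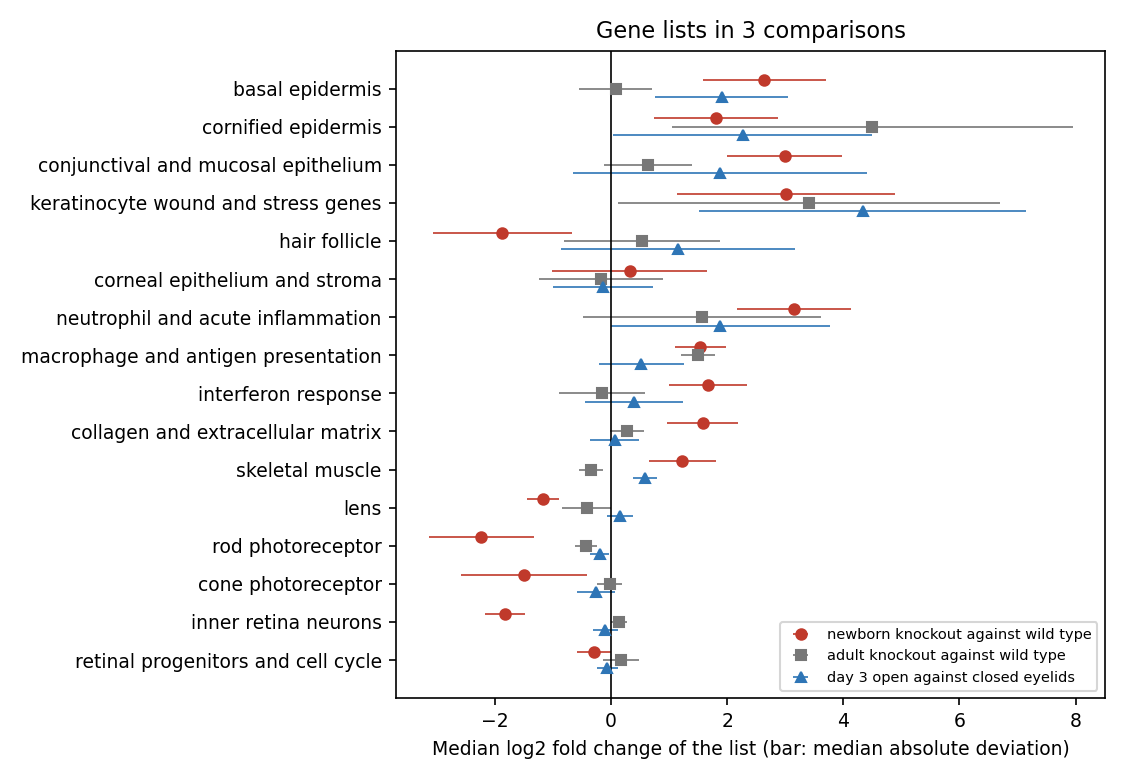
Median log2 fold change (x axis) of 16 gene lists (y axis) in newborn and adult labelled-knockout against wild-type eyes and in open against closed day 3 eyes, with bars for the median absolute deviation. The median of basal epidermis was 2.64 in newborn, 0.08 in adult and 1.90 in open eyes, and that of rod genes was -2.23 in newborn eyes.

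The adult comparison asked the same of adult eyes, with 2 labelled-knockout libraries against 1 wild type. Crabp2, a carrier of retinoic acid, stood at 30.5 ± 4.30 CPM (mean ± SD) against 2.84 CPM, a log2 fold change of 3.44 ± 0.27 (adjusted p = 0.0653). Klk10, a serine protease of epithelia, had 251 ± 38.3 CPM against 4.86 CPM, and Krtdap differed by 6.31 ± 0.69. Sprr1b, with 2 reads in the wild type, was higher 748-fold (95% interval 207 to 6176), and Lce3b, with 1 read, 619-fold (95% interval 111 to 24480). Lower in the labelled knockout were Ppp1r3c (-1.55 ± 0.23), Alb (-4.79 ± 0.74), Oas2 (-1.97 ± 0.34), Kit (-1.26 ± 0.24) and Gyg (-1.04 ± 0.21). No gene passed with edgeR, while DESeq2 called 107. By edgeR 506 of 17592 genes had an unadjusted p under 0.05, fewer than the share of 0.05 that chance alone would give. The corneal keratin Krt12 was at 2.64 CPM in labelled-knockout replicate 1, 3860 CPM in replicate 2 and 6411 CPM in the wild type. The count was 49 without adult labelled-knockout replicate 1, 205 without replicate 2, and 13 and 3 without newborn labelled-knockout replicate 1 or 2.

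Of 47 keratinocyte wound and stress genes, 45 were higher in adult labelled-knockout eyes (median 3.41, or 2.98 with genes at 0 reads set to their bound). None passed over all genes (edgeR), 26 passed adjusted over the list alone, and the list had adjusted p = 0.0132 with an estimated correlation. That call was lost when any 1 library other than the adult wild type was left out, with adjusted p from 0.103 (newborn wild-type replicate 1) to 0.187 (adult labelled-knockout replicate 2), while the median stayed at 3.34 or above. S100a9 had a value of 4.44 ± 0.50. The cornified epidermis list had a median of 4.50 (3.51 with bounds) and 19 genes passing adjusted over the list alone (adjusted p = 0.568 with an estimated correlation). For neutrophil genes the median was 1.57 (1.33 with bounds; 4 adjusted over the list alone; adjusted p = 0.568 with an estimated correlation), with S100a8 at 4.57 ± 0.76. Macrophage genes had a median of 1.49 (0 adjusted over the list alone; adjusted p = 0.797 with an estimated correlation). These medians leaned on 1 library: without labelled-knockout replicate 1 they were 0.82 (neutrophil) and 0.36 (macrophage), and without replicate 2 they were 2.06 and 1.99. Basal epidermis had a median of 0.08 and a mean of 0.04, while its rank among all genes was downward (list adjusted p = 0.653). Its median was 0.33 without labelled-knockout replicate 1 and -0.28 without replicate 2.

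Over both ages, with age as a term (n = 4 against 3), 2 genes of 17592 passed (edgeR, 3667 at an unadjusted p under 0.05, DESeq2 1486). S100a9, a calcium-binding protein of neutrophils and stressed epidermis, rose by 4.56 ± 0.30 (adjusted p = 0.019) and was higher in all 4 labelled-knockout libraries than in the 3 wild types. Its means were 20.4 ± 7.65 CPM in newborn and 20.6 ± 3.25 CPM in adult labelled knockouts, against 0.803 ± 0.195 CPM in newborn and 0.963 CPM in adult wild types. Sprr1b rose by 8.31 ± 0.58 (adjusted p = 0.019). S100a8 (4.31 ± 0.43), Il24 (5.85 ± 0.63) and Sprr2f (4.34 ± 0.49) did not pass (adjusted p = 0.1 each), nor did Atoh7 (-2.21 ± 0.35), Fam116b (-0.92 ± 0.16), Kif21b (-0.99 ± 0.17), Gpc2 (-1.08 ± 0.19) and Hmgn2 (-0.97 ± 0.18). Of 47 wound and stress genes, 2 rose (median 2.70; 37 adjusted over the list alone), and the call held with an estimated correlation (adjusted p = 0.00716), though not without the adult wild type (adjusted p = 0.0786). The count was 0 without newborn wild-type replicate 1, wild-type replicate 2 or labelled-knockout replicate 2, 147 without adult labelled-knockout replicate 2, and 4502 without the adult wild type, where only the newborn libraries inform the contrast.

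The difference of the genotype effect between ages was tested itself. The effect was lower in adult than in newborn eyes for Lama3 (-4.86 ± 0.39, with 3.60 in newborns and -1.25 in adults), the integrin Itgb4 (-4.33 ± 0.43), Clca4 (-6.48 ± 0.71) and Psca (-7.94 ± 1.42). Klk10 had a higher effect in adults (3.71 ± 0.59), as did the glycine receptor subunit Glra2 (2.89 ± 0.42), with a newborn value of -2.45. The effect was higher in adults for 175 genes and lower for 317 of 17592 (edgeR; DESeq2 2131 in all). Of 27 basal epidermis genes, 9 were lower (22 adjusted over the list alone), of 37 inner retina genes 11 were higher (25 adjusted over the list alone), and of 29 interferon genes 7 were lower (15 adjusted over the list alone). Each list had adjusted p = 0.592 with an estimated correlation. The count was 0 without newborn wild-type replicate 1 or 2 (edgeR), 109 without newborn labelled-knockout replicate 1 and 1346 without replicate 2, and 1401 and 1613 without adult labelled-knockout replicate 1 or 2. With the authors' library totals, 98 genes were higher and 352 lower.

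Across 17592 genes, the log2 fold changes at the 2 ages had a Pearson r of 0.106 and a Spearman correlation of 0.114, a description across genes, which are not independent replicates. Without newborn labelled-knockout replicate 1 the Pearson r was 0.00995, without newborn wild-type replicate 1 it was 0.2932, and without wild-type replicate 2 it was 0.0478.

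Adult and newborn labelled-knockout eyes were compared for age (n = 2 each). Photoreceptor genes were far higher in adults. Gnat1, rod transducin, rose by 13.27 ± 0.99 and Pde6a by 9.33 ± 0.35, and Rpe65, the isomerase of the visual cycle, by 10.33 ± 0.78. Of 37 rod genes, 36 rose (median 6.01; 36 adjusted over the list alone; adjusted p = 0.628 with an estimated correlation). Of 40 progenitor and cell cycle genes, 38 fell (median -2.36; 39 adjusted over the list alone; adjusted p = 0.628 with an estimated correlation), with Neurog2 at -3.65 ± 0.19. Of 45 collagen and matrix genes, 36 fell and 2 rose (median -2.26; 36 down and 2 up adjusted over the list alone; adjusted p = 0.628 with an estimated correlation), with Fbn2 at -4.90 ± 0.23. Cplx4 (9.09 ± 0.34) and Grk1 (8.95 ± 0.81) rose as well, and Sebox and Bhlhe23, with 1 read each in newborns, were higher 1451-fold (95% interval 259.8 to 57350) and 1281-fold (95% interval 229 to 50660). Single libraries set 2 other values. Abpz rose by 8.91 ± 2.27, but by 2.21 without adult labelled-knockout replicate 1, where it did not pass (adjusted p = 0.151), and it did not pass without any 1 of the newborn libraries (highest adjusted p = 0.0869, without labelled-knockout replicate 2). Cryge fell by 11.05 ± 2.67, with 29.1 and 5959 CPM in the newborn labelled knockouts, and by 4.36 without newborn labelled-knockout replicate 2. It did not pass without newborn wild-type replicate 1 or 2 (adjusted p = 0.0519 and 0.0531).

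At 0 reads in both adult labelled knockouts were Srp54b, lower by at least 401-fold, Hist1h2ao (369-fold), Il11ra2 (261-fold), Sema6b (231-fold), Dzip1 (222-fold), Plac9 (151-fold), Olig2 (139-fold), Sprr2a (125-fold) and Ggh (116-fold), each a lower bound. All but Olig2 (12 reads) were at 0 reads in the adult wild type too. Rpl24 stood at 0.225 ± 0.0559 CPM in adults and 47.0 ± 1.57 CPM in newborns, and Rps6 at 1.35 ± 0.0798 and 59.9 ± 3.72 CPM. In all, 3404 genes rose and 3581 fell of 17592 (edgeR). Whether reads with several alignments were counted alike at both ages was not tested, so the values at or near 0 do not by themselves show a loss of expression. The labels give no batch, so that age cannot be told apart from processing at another time. Age also overlapped with sex as read from Y-linked genes. Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in both adult labelled knockouts. In the newborn labelled knockouts they had 827, 352, 491 and 300 reads, those of Ddx3y nearly all in replicate 2.

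At day 3, open eyes were compared with closed eyes within mice, E24 and E29 informing the contrast. Keratins of activated epidermis were higher in open eyes. Krt6b rose by 4.16 ± 0.17 (log2 fold change ± SE), with 998 ± 200.4 CPM in 4 open eyes (mean ± SD) and 47.1 ± 4.61 CPM in the 2 closed eyes of labelled knockouts. Krt16 rose by 4.67 ± 0.29, Krt14 by 3.92 ± 0.28 and Krt6a by 3.67 ± 0.22. Envelope precursors rose too, with Sprr1a at 8.13 ± 0.41 and Sprr1b at 6.30 ± 0.57, as did Ppbp (7.64 ± 0.52), Psca (5.41 ± 0.51), Nccrp1 (6.04 ± 0.69) and arginase 1 (Arg1, 5.10 ± 0.57). With 1 or 2 reads in the closed eyes of E24 and E29, and in reads summed over these mice, Cnfn was higher in their open eyes 664-fold (95% interval 119 to 26240), Sprr3 402-fold (95% interval 71.7 to 15900), Il1b 245-fold (95% interval 43.7 to 9723) and Abpe 147-fold (95% interval 40.5 to 1222). Abpe had 4 reads in the open eye of E24 and 318 in that of E29. Krt12, the keratin of corneal epithelium, fell by 1.41 ± 0.21, with 34.2 ± 7.35 CPM in open and 107 ± 18.5 CPM in closed eyes of labelled knockouts. Atp6v1c2 (-4.60 ± 0.57), Cdc40 (-2.31 ± 0.16), Wdr45 (-2.30 ± 0.17), Prdm4 (-1.58 ± 0.14), Ubr2 (-1.38 ± 0.14), Tmem178 (-1.30 ± 0.18) and Commd5 (-1.28 ± 0.14) fell. Of these, Cdc40, Wdr45, Prdm4, Ubr2 and Commd5 stepped sharply between eyelid states, and for such genes a batch remained open, as described below. Egr1 differed by 0.25 ± 0.16 (adjusted p = 0.999).

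In all, 72 genes rose and 9 fell of 15754 tested (edgeR, 985 at an unadjusted p under 0.05, DESeq2 369). In total the 985 genes lie little above the share of 0.05 that chance alone would give. Of them, 885 were higher and 100 lower in open eyes, while chance would split independent genes about evenly. The count was 0 without E24 (edgeR, 845 at an unadjusted p under 0.05), 1 without E29 (389), 129 without E32, 50 with the mouse as a random effect and 210 in E24 and E29 alone. The order of the libraries' laboratory numbers follows the eyelid state, so that a batch and the eyelid state cannot be told apart by the labels.

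Of 39 keratinocyte wound and stress genes, 8 rose in open eyes (median 4.33; 31 adjusted over the list alone). With genes at 0 reads set to bounds over all 8 eyes, E32 and E28 included, the median was 4.16, which mixes changes within and between mice. The list had adjusted p = 0.0158 with an estimated correlation. That call was lost without any 1 mouse, with adjusted p = 0.173 (E24), 0.139 (E28), 0.0834 (E29) and 0.334 (E32). Of 27 basal epidermis genes, 11 rose (median 1.90; 21 adjusted over the list alone; adjusted p = 0.298 with an estimated correlation), with Lamb3 at 2.99 ± 0.26, Sfn at 2.92 ± 0.23 and Dsg3 at 2.68 ± 0.23. Of 25 conjunctival and mucosal genes, 4 rose (median 1.88; 14 adjusted over the list alone; adjusted p = 0.298 with an estimated correlation), with Krt4 at 3.10 ± 0.26, Krt7 at 1.88 ± 0.22 and Krt13 at 4.38 ± 0.58. Of 52 cornified epidermis genes, Cnfn, Tgm1 (2.50 ± 0.25) and Asprv1 (3.14 ± 0.36) rose (median 2.26; 18 adjusted over the list alone; adjusted p = 0.365 with an estimated correlation). With bounds over all 8 eyes the median was 3.06, which is not a bound of the change within E24 and E29. Krt10, of suprabasal epidermis, was at 1977 and 666 CPM in the eyes of E32 and at 13.9 and 14.5 CPM in the open eyes of E24 and E29. Without E24 none of these lists had a passing gene (edgeR), and without E29 only 1 wound and stress gene passed. Without E32 the conjunctival and cornified counts were 7 and 5.

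Of 41 neutrophil and acute inflammation genes, 2 rose in open eyes (median 1.88; 10 adjusted over the list alone; adjusted p = 0.298 with an estimated correlation), and of 10 lacrimal and exocrine genes, the potassium channel Kcnn4 rose by 2.89 ± 0.37 (median 2.62; 3 adjusted over the list alone; adjusted p = 0.298 with an estimated correlation). None of 53 skeletal muscle genes passed (median 0.59; 0 adjusted over the list alone; adjusted p = 0.713 with an estimated correlation), and none of 33 macrophage genes did (median 0.52; 0 adjusted over the list alone; adjusted p = 0.298 with an estimated correlation). Of 30 immediate-early genes, 0 passed over all genes and 3 adjusted over the list alone, among them Junb at 1.29 ± 0.25 (median 0.40; adjusted p = 0.282 with an estimated correlation). No eyelid closure gene passed (42 measured, median 0.06, list adjusted p = 0.122), and none of 36 rod genes did (median -0.20, list adjusted p = 0.0732). The passing genes of the neutrophil list were lost without E24 or E29, leaving 0 by edgeR. At the preset correlation 11 of the 30 lists passed upward and 2 downward for the eyelid (camera). With an estimated correlation 1 passed.

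**Figure D3:**
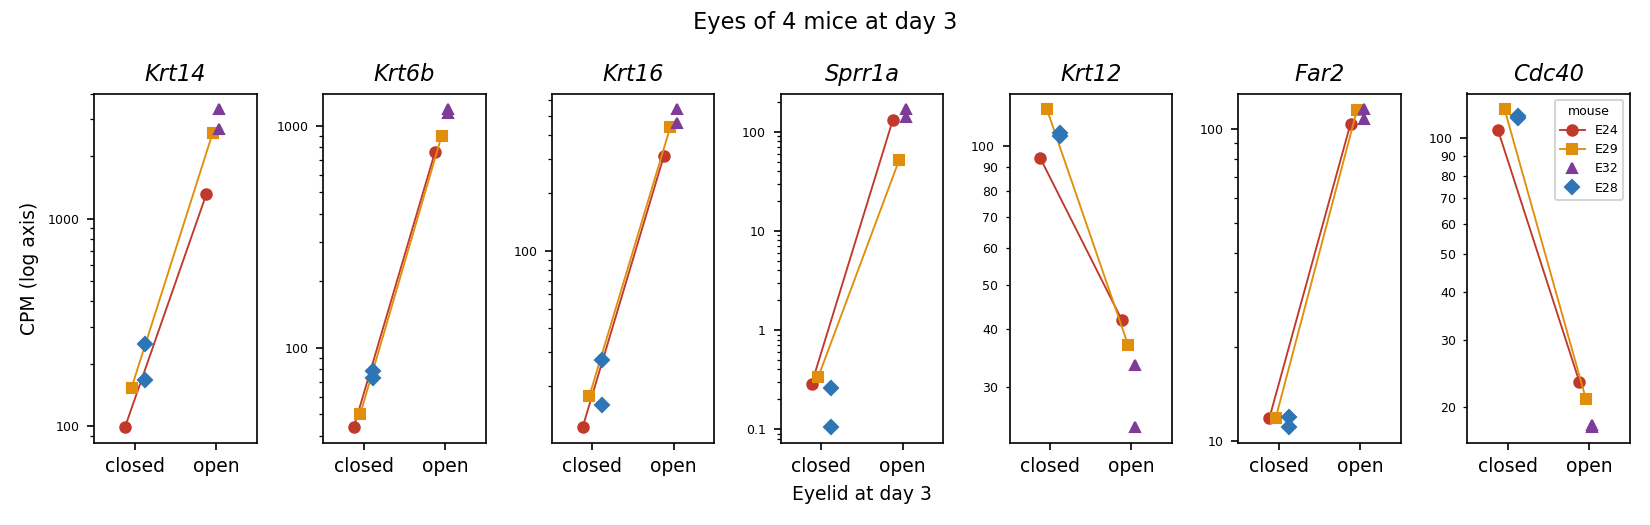
Levels (CPM, log axis) of 7 genes in closed and open eyes at day 3 (x axis), by mouse (colour and shape), with lines joining the eyes of E24 and E29. Krt14, Krt6b, Krt16, Sprr1a and Far2 were higher in the open eye of both mice, and Krt12 and Cdc40 lower.

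Labelled-knockout mice were compared with the heterozygous mouse at day 3 (n = 3 against 1 mice). Egr1 had a value of 1.35 ± 0.54 (adjusted p = 0.999). Sprr1b, at 0 reads in both heterozygous eyes, was at least 248-fold higher in labelled knockouts, and Sprr1a differed by 8.93 ± 1.68. Mmp3, a stromelysin with 3 reads in the heterozygous mouse, was higher 69.6-fold (95% interval 23.7 to 338), and Ppbp, with 2 reads, 811-fold (95% interval 224 to 6695). Most of these were values of the open eyes. Closed eyes of labelled knockouts had 7 and 8 reads of Sprr1a (3 and 6 in heterozygous eyes), 10 and 1 of Sprr1b and 3 and 7 of Ppbp, against at least 1388, 282 and 450 in open eyes. For Mmp3 they had 0 and 63 reads, against 68 to 252. Far2, a fatty acyl-CoA reductase, differed by 2.83 ± 0.54 and was at 11.8 and 11.9 CPM in closed eyes of labelled knockouts and at 11.1 and 11.96 CPM in heterozygous eyes. Values higher in the heterozygous mouse rested on its right eye. Right and left eye had 6.94 and 0.350 CPM of Rtp3 (-5.05 ± 0.89), 11.6 and 0 CPM of Amica1 (-3.62 ± 0.70) and 8.90 and 0.175 CPM of Sp100 (-2.64 ± 0.54). Spata3, at 0 reads in labelled knockouts, had 10.1 and 0.0438 CPM (at least 292.3-fold over both), and Ccl20, with 1 read in labelled knockouts, had 97 and 0 reads (293.4-fold (95% interval 51.4 to 11700) over both). None passed: 0 of 16453 genes were called by edgeR (smallest adjusted p 0.999), while DESeq2 called 96. By edgeR 273 genes had an unadjusted p under 0.05, fewer than the share of 0.05 that chance alone would give. The wound and stress list had a median of 4.80 (3.41 with bounds), the cornified list one of 6.75 (4.48 with bounds) and the muscle list one of 1.03, each with 0 genes passing adjusted over the list alone and adjusted p = 0.731 with an estimated correlation. The heterozygous eyes were both closed and 4 of the 6 labelled-knockout eyes open, so that genotype and eyelid state overlap here. Without E32, 6 genes passed.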

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

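The quantities tested for a distant eye were chosen after the data had been seen, while the test of the difference between ages was planned. Knockout means labelled knockout throughout, since Egr1 reads went against the labels.

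The difference of the genotype effect between ages passed for 492 genes (edgeR, adult minus newborn, log2). Among genes with a higher effect in adults were Mt4, a metallothionein of stratified epithelium (10.49, at 0 reads in the adult wild type and at least 48.8-fold higher in adult knockouts), Serpinb3b (9.32, at 0 reads in the adult wild type, at least 59.8-fold) and Psors1c2 (8.11, 1 read in the adult wild type, 161-fold (95% interval 28.7 to 6387)). Then came the ichthyosis gene Nipal4 (4.09), Sebox (4.02), Klk10 (3.71), Aox4 (3.44), Otop3 (3.12), Tcfap2d (2.96) and Glra2 (2.89). The fitted difference of 9.32 for Serpinb3b, like that of Mt4, rests on a group at 0. Lower in adults were Psca (-7.94), Clca4 (-6.48), the epithelial proteases Prss22 (-5.16) and Prss27 (-5.05), Lama3 (-4.86), Nccrp1 (-4.72), Sectm1b (-4.36), Itgb4 (-4.33) and Mag (-4.08). The 492 genes became 0 without newborn wild-type replicate 1 or 2, 109 without newborn knockout replicate 1, 1346 without newborn knockout replicate 2, and 1401 and 1613 without adult knockout replicate 1 or 2.

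By list, the median difference between ages was negative for basal epidermis (-2.49), conjunctival and mucosal genes (-2.36), interferon response (-1.73), skeletal muscle (-1.50), neutrophil and acute inflammation (-1.45), corneal genes (-1.33), collagen and matrix (-1.21), glucocorticoid-responsive genes (-0.83), immediate-early genes (-0.61), eyelid closure genes (-0.60), circadian genes (-0.53), Wnt signaling (-0.43) and hedgehog, FGF and BMP signaling (-0.30). It was positive for cornified epidermis (3.52), hair follicle (2.48), inner retina (1.97), rods (1.88), cones (1.60) and retinal progenitors (0.56). The positive values of the 2 skin lists rested in part on genes at 0 reads in an adult group, 13 of 55 in cornified epidermis (adult median 4.50, or 3.51 with bounds) and 14 of 41 in hair follicle (0.53, or 0.25 with bounds). The newborn median of cornified epidermis was -0.81 without newborn labelled-knockout replicate 1, so that its difference between ages rose to 5.30, and that of hair follicle fell to 1.24 without newborn wild-type replicate 2. When single libraries were left out, the others kept their sign, while progenitors ranged from 0.11 to 0.78, rods from 1.31 to 2.65, cones from 1.24 to 2.49, corneal genes from -2.31 to -0.77, muscle from -2.45 to -1.06, neutrophil genes from -2.03 to -0.83, circadian genes from -0.83 to -0.43, Wnt signaling from -0.72 to -0.25 and hedgehog, FGF and BMP signaling from -0.59 to -0.29. At the preset correlation 4 lists then failed to pass in some of these fits, with a highest adjusted p of 0.180 (progenitors), 0.0798 (glucocorticoid-responsive), 0.115 (Wnt) and 0.142 (hedgehog, FGF and BMP). With an estimated correlation none of these lists passed, with adjusted p = 0.592 for most, 0.595 for cornified epidermis, Wnt and hedgehog, FGF and BMP signaling, and 0.612 for progenitors. Under the authors' library totals the median over all genes moved from 0.08 to 0.01, less than each of these medians.

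Among the 4 open eyes, the mean level (log2 CPM) of 5 lists out of 50 tested quantities had 1 eye far from the others, where chance alone gives about 1 in 20 for independent eyes. The 2 eyes of E32 share a mouse, so that this rate holds only roughly here. The right eye of E24 was low in skeletal muscle (5.03 against 5.50 to 5.58), in lacrimal and exocrine genes (0.94 against 3.97 to 4.57), in circadian genes (4.63 against 4.71 to 4.72) and in glucocorticoid-responsive genes (4.19 against 4.83 to 4.93). The left eye of E32 was high in collagen and matrix genes (8.35 against 7.83 to 7.89). No explanation was tested for these eyes.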

How the results depend on the processing

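Added after the data had been seen were the authors' library totals, all transcripts and libraries without lens genes. Of the alternatives of the main results, 105 stayed the same. For counts this meant within 1.5 times, for Egr1 the same direction and side of the threshold, and for the correlation a value within its spread. Another 22 passed where the result had not or gave over 1.5 times the count, and 14 gave a count lower by over 1.5 times. The other 2, values without a test, moved by more than their spread. For named genes 522 kept direction and side of the threshold, 34 passed where the main fit had not and 76 no longer passed. The direction reversed for 1, Egr1 between adult and newborn eyes (0.0919 at the highest when single libraries were left out, -0.15 with all, passing in neither). With DESeq2 the counts were 107 (adult), 1486 (both ages), 2131 (difference between ages), 369 (eyelid) and 96 (heterozygous), and Egr1 over both ages passed at 2.38. Adult counts were 13 without a filter and 33 with the authors' totals. The count over both ages was 1 with a replicate block. The eyelid count was 50 with the mouse as a random effect and 210 in the mice with 1 open and 1 closed eye. With an estimated correlation 3 lists passed in place of 128, and 108 to 133 did under the other settings. Fry, not counted among these settings, passed 13 lists in newborn eyes, 1 in adult eyes, 1 over both ages and 0 for the difference between ages. It passed 10 for age, 2 for the eyelid and 0 for the heterozygous mouse. The correlation between ages was 0.269 at a mean of at least 5 RPKM, where fewer genes were tested. For the other changes the cause was not tested. Leaving out single libraries or mice gave 0 to 5116 genes (newborn), 0 to 205 (adult), 0 to 4502 (both ages), 0 to 1613 (difference between ages), 5003 to 7351 (age), 0 to 129 (eyelid) and 0 to 6 (heterozygous), 2.15 to 2.58 for Egr1 over both ages, 116 to 133 lists and 0.00995 to 0.2932 for the correlation. Counts of 0 are those of edgeR. Without newborn wild-type replicate 1, 4735 newborn genes had an unadjusted p under 0.05. Alternatives with another pseudocount, planned for RPKM alone, were not run. Of 100 simulated genes changed 2-fold, 17 were recovered in the newborn design, 3 in the adult and eyelid designs and 0 for the heterozygous mouse. Most 2-fold changes are thus likely missed in the adult, eyelid and heterozygous comparisons. Few genes were changed in these runs, so that the adjusted threshold was stricter than in the newborn data, where 4226 genes were called. The newborn recovery therefore does not carry over to those data.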

Other observations

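All tests of explanations in this part were chosen after the result was seen, except those for linkage to Egr1, for sex by the Xist level, for time of day and for skin and muscle in open eyes.

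In further lists, single genes changed in newborn labelled-knockout eyes. Of 24 corneal genes, 9 rose (median 0.32; 11 adjusted over the list alone; adjusted p = 0.621 with an estimated correlation), with Ecm1 at 3.36 ± 0.33 and the stromal proteoglycan Lum at 1.37 ± 0.25. Of 18 glucocorticoid-responsive genes, 7 rose (median 1.26; 10 adjusted over the list alone; adjusted p = 0.451 with an estimated correlation), with the EGF receptor inhibitor Errfi1 at 1.55 ± 0.16 and the metallothioneins Mt1 at 1.42 ± 0.17 and Mt2 at 1.88 ± 0.23. In Wnt signaling 13 rose and the Wnt inactivator Notum fell by 2.38 ± 0.29 (46 genes, median 0.45; 15 up and 1 down adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). In hedgehog, FGF and BMP signaling 11 rose and 2 fell, with follistatin (Fst) at 1.83 ± 0.24 and Fgf7 at 2.16 ± 0.35 (44 genes, median 0.49; 12 up and 2 down adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). The lacrimal list did not pass, and 4 of its 14 genes rose, with Aqp5 at 2.87 ± 0.70 (median 2.13, list adjusted p = 0.156; 4 adjusted over the list alone). Without 1 gene that had at most 3 reads in each group, the median was 2.30. The corneal median was 0.97 and the Wnt median 0.77 without newborn wild-type replicate 2. All counts of newborn genes were 0 by edgeR without newborn wild-type replicate 1 (4735 at an unadjusted p under 0.05).

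Other newborn lists went both ways or held few genes that passed. Meibomian and sebaceous lipid genes had 7 up, among them Dgat2 (1.36 ± 0.27), and 1 down of 34 (median 0.09, list adjusted p = 0.337). Muller glia and astrocyte genes had 3 up and 4 down of 22, with Hes5 at -2.12 ± 0.25 and Abca8a at 1.82 ± 0.29 (list adjusted p = 0.868; its median was 0.00 and its mean -0.10). Pigment genes had 2 up, with Sox10 at 2.77 ± 0.32, and 1 down of 27 (median -0.07, mean 0.02, list adjusted p = 0.978), and red cell genes 1 up and 2 down of 17, with Car2 at -1.93 ± 0.27 (list adjusted p = 0.744). Of 19 circadian genes 6 rose and Arntl fell by 1.33 ± 0.21 (median 0.55; 8 up and 1 down adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). None of 7 Y-linked genes and Xist passed (list adjusted p = 0.421; median -0.89, mean 0.72). Of 95 listed genes on chromosome 18 near Egr1, 12 rose and 9 fell (median -0.14, list adjusted p = 0.579). Of 10 genes known to differ between BALB/c and C57BL/6, 3 rose, with Ifi202b at 3.40 ± 0.50 and Nnt at 0.66 ± 0.18 (median 1.09; adjusted p = 0.382 with an estimated correlation).

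Several levels differed from what their gene would lead to. Gapdh was at 1.05 to 2.94 CPM in every library, for which no cause was tested. Xist was at 340 CPM in newborn labelled-knockout replicate 1 and at 618 to 717 CPM in the 3 adults, while the Y-linked Ddx3y was at 0.0667 CPM in that newborn library and at 22.1 to 31.7 CPM in the other newborns. Newborn wild-type replicate 1 had a library total of the authors 1.32 times the sum of its reads and 397 transcripts at 0 reads, against 1278 to 1739 in the other newborns.

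Genes called between newborn labelled-knockout and wild-type eyes were weighed first. Skin carried whole with the eyes, hair follicles included, was argued against, since the median of basal epidermis exceeded that of hair follicle by 4.51 log2. Without newborn wild-type replicate 2 the difference was 3.60, still over the sum of the 2 median absolute deviations (2.16). Epidermis or muscle carried without hair follicles stayed open. The medians of cornified epidermis (1.81), collagen and matrix (1.58) and skeletal muscle (1.23) rose with that of basal epidermis (2.64). For a smaller share of retina, progenitors exceeded rods by 1.94, and by 1.62 (sum 1.13) without newborn labelled-knockout replicate 1. That difference cannot decide, because the progenitor list also holds cell cycle genes, which dividing cells of other tissues may express. Rod, cone and inner retina medians all fell (-2.23, -1.50 and -1.83), as did single progenitor genes such as Neurog2. A smaller share of retina therefore stayed open. Xist was high in 1 of the 2 newborn labelled knockouts (340 CPM), and sex was argued against as the whole cause for the 2068 calls kept without that library. For the 2158 lost it stayed open. Their median fold was 0.87 (median absolute deviation 0.32) without that library against 1.03 (0.42) with it, so that the calls ended with a smaller fold, and their median SE went from 0.24 to 0.29 with 1 library fewer. That fold does not decide, because in 100% of the lost calls the other labelled knockout lay beyond both wild types from the start. Linkage could not be decided: 25.1% of genes within 20 Mb of Egr1 were called and 24.9% elsewhere (Fisher's exact one-sided p = 0.496), and its 58 of 3782 calls leave nearly all others without it. Time of day stayed open (Dbp 0.21 ± 0.20, Nr1d1 -0.44 ± 0.20, both inside the planned limit of 0.5 log2, though Nr1d1 lay within its SE of that limit), as did litter and backcross generation, which were not tested.

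Egr1 reads above wild type in every labelled knockout formed the second pattern. A rise shared equally by immediate-early genes was argued against, since the median of the others was 0.87 over both ages and none of 30 reached Egr1. In newborn eyes 7 of 30 did (median 0.98), so that a stronger response of some members, Egr1 among them, stayed open. Exchanged labels remained open, as the lowest labelled-knockout level was 157 CPM and the highest wild-type level 60.7 CPM, and heterozygous eyes lay between at 105 CPM. A disrupted allele that still makes reads, without protein to restrain its own gene, may give the same levels and was not tested. Over both ages, 3 of 34 fitted splits of the 7 libraries, the real one included, gave at least the real count of 2 genes. The others gave 226 and 5 genes. The split with 226 set adult knockout replicate 1 and both newborn knockouts apart, a structure of the samples. That with 5 set adult knockout replicate 2 and both newborn wild types apart. Both thus hold the newborn genotype difference, so that they do not decide whether chance gave the 2 genes.

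Genes called between open and closed eyes formed the third pattern. A batch that follows the eyelid state remained open for 19 genes that stepped sharply between states (1 log2, SD at most 0.25, limits set after Far2, Ergic2 and Cdc40 were seen), against at most 8 in the other splits of 35. Among them Far2 was at 110 against 11.7 CPM, Ergic2 at 120 against 23.6 CPM and Cdc40 at 20.04 against 113 CPM, and none passed in newborn eyes. Of the 19 genes, 14 were among those called between open and closed eyes. For the 63 other genes higher in open eyes a batch in library processing alone was argued against. Of these genes 60 also rose in newborn labelled-knockout eyes, where 10.3 were expected. That overlap does not decide on a batch in which more skin was carried with the open eyes. Skin and muscle carried with the eye stayed open: medians were 1.90 (basal), 2.26 (cornified), 1.15 (hair follicle) and 0.59 (muscle), a span of 1.68. Of 72 genes higher in open eyes 60 rose in newborn labelled-knockout eyes (11.8 expected, Fisher's exact p = 6.98e-36). Of 9 genes lower in open eyes 0 fell there (0.93 expected). The Fisher test takes genes as independent, which genes that move together are not. Such an overlap would follow from 1 epithelial response to exposure or injury, a hypothesis found and tested on the same data. It cannot be told apart from more skin or epithelium in both sets of eyes.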
